A study of Mus musculus with 2 samples.

How the data were processed

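H3K36me3 was measured by ChIP-seq in hearts of B6NCrl mouse embryos at embryonic day 12.5, with male and female embryos pooled. Per the labels the libraries were selected for sizes of 300 to 500, and the 2 samples are biological replicates of 1 group. Replicate 1 combined 2 technical replicates and replicate 2 had 1, and technical replicates were not counted as replicates here.

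The 4 deposited peak lists were used, all in narrowPeak format on mm10. Per the notes deposited with them, each replicate's list was called on that replicate's filtered alignments, the pooled list on the alignments of both replicates, and the replicated list was made from the other lists. Replicate 1 was called with 2 further input files, replicate 2 with 1 and the pooled list with 2. The controls and the alignments themselves were not analysed here. The aligner, the peak caller and its threshold, the rule of replication and the number of reads were not given in the sources used here. The display score and the signal value (a score whose scale is not stated) of each peak are the authors' own and were not rescaled. The −log10 p and −log10 q of each peak are as deposited by the authors, with a smallest −log10 p of 2.01 to 2.03 over the 4 lists. Every replicated peak was found in the pooled list, and no peak overlapped another within a list. The read depth being unknown, no counting interval or detection limit was computed. With 2 replicates the SD is itself imprecise.

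Genes were taken from GENCODE release M21 on GRCm38, the same assembly as mm10, and the lengths of the 21 chromosomes were checked against the reference sequence. The 21911 protein-coding genes on chromosomes 1 to 19, X and Y were used, of which 21.5% overlap another. Sequence without undetermined bases came to 2648 Mb. The covered share of a gene is the percentage of the bases from its annotated start to its end that lie in peaks. A gene was called marked at 10% or more by replicated peaks. Values by replicate come from that replicate's own list, and their mean and SD (n = 2) are given beside the value of the replicated list. Promoters were the 1 kb upstream of protein-coding genes, counted only where it lay outside every annotated gene body. Gene body profiles used genes of at least 5 kb in 10 equal parts with flanks of 10 kb in 1 kb steps. Exons were compared with introns within marked genes of at least 5 kb, leaving out the first of each.

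Peaks were called shared between replicates at an overlap of 1 bp. Chance levels came from 100 circular shifts of the peaks within each chromosome, outside the first 3 Mb. There were 22 gene lists with 477 matched members, 1 symbol that matched no gene and 2 matched by a synonym. Added to these were the genes whose symbols are Olfr or Zfp followed only by digits. Each list was compared with 10000 random lists of the same size, matched on 10 classes of gene length. The 3 cardiac muscle lists (sarcomere, transcription factors, calcium handling and conduction) were compared with 5 other-tissue lists (neuronal, hepatocyte, skeletal muscle, kidney and gut, germ cell and pluripotency). This used a two-sided permutation test with 100000 resamples over genes, and Fisher's exact test for the marked counts. No other p-value was computed. The lists, the 10% level, the comparisons and all the alternatives below were fixed before the data were examined.

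Genes were named by a rule fixed at the same time. It took from each list the 2 members with the highest and the 2 with the lowest covered share by replicated peaks, with ties going to the longer gene. It also took the 20 genes of at least 10 kb with the highest covered share, the 10 with the most covered bases, the genes at the 10 peaks of highest signal value and at the 5 widest. The 10 genes of at least 10 kb that differed most between the replicates, 5 each way, and 15 genes named in advance completed it. Genes outside the rule, such as overlapping neighbours and members that make up a small count, were chosen after their values were seen.

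The alternatives were the pooled list, peaks with a −log10 p of at least 5, either replicate's list alone, the top 50000 peaks of each list, and an overlap of 50% of the shorter peak. Others were a level of 1 bp or 25% of the gene body, genes that overlap no other, genes of at least 5 kb or 20 kb, random lists of any length, and peak midpoints in place of bases. Peaks on sequences outside chromosomes 1 to 19, X and Y were left out of the comparisons.

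The procedures were tested on simulated data. All 200 genes planted with peaks at known levels were called marked (100%), with a largest error of 0.00998 percentage points in the covered share. Every planted level was above 10%, so the 100% was fixed in advance and measures no sensitivity. Of 10807 other genes of at least 10 kb that overlap no other coding gene, 0% were called marked. No peak was placed in these genes, so this value was fixed in advance and gives no rate of false calls. A planted 60% of shared peaks was recovered as 60%. The other peaks were placed where they could not overlap, so this value checks only the computation. Of 200 random lists 4% fell outside their range, and lists planted with 90% marked genes lay above it in 100% of cases. With no difference planted the permutation test fell under 0.05 in 6.5% of 200 simulations, and with a difference of 20 points in 99.5%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.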

Results

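Trimethylation of lysine 36 of histone H3 (H3K36me3) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the heart of B6NCrl mouse embryos at embryonic day 12.5. H3K36me3 is known as a mark laid down by Setd2 over the bodies of transcribed genes. The series held 1 group of 2 biological replicates, each from pooled male and female embryos, so no condition was compared and the comparisons below are between genes, regions and replicates. The deposited values were lists of peaks on the mm10 assembly. Replicate 1 had 221326 peaks covering 135.8 Mb, or 5.13% of the sequenced genome, and replicate 2 had 203005 peaks covering 107.6 Mb, or 4.06%. A list called on both replicates together held 214845 peaks over 151.1 Mb, and its subset of replicated peaks held 150671 peaks over 135.2 Mb. Read depth was not given in the sources used here, so no counting interval accompanies the values. The covered share of a gene is the percentage of its body, from annotated start to end, that lay inside peaks. A gene with at least 10% of its body inside replicated peaks is called marked. Members of a list are ranked by replicated peaks, and the covered shares printed with an error are means of the replicates. Errors are the SD of the 2 replicates' own lists (n = 2) throughout, and a covered share of 0 means only that no listed peak touched the gene.

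The first question was whether genes of the heart carried the mark and genes of other tissues did not. Genes of the cardiac sarcomere, the contractile unit of heart muscle, were marked in 23 of 24 cases, and the same number was found in each replicate. Mybpc3, which encodes cardiac myosin-binding protein C (chromosome 2, 91118144 to 91136516), had a covered share of 85.9% ± 5.23 (SD, n = 2). The myosin heavy chain genes Myh6 (chromosome 14, 54941921 to 54966927) and Myh7 (54970684 to 54994626) had covered shares of 72.6% ± 9.59 and 62.8% ± 11.1. Tnnt2, encoding cardiac troponin T, was covered to 74.3% ± 6.69, Ttn, encoding the giant protein titin, to 69.8% ± 4.40, and Actc1, encoding cardiac actin, to 36.6% ± 0.316. The lowest members were Myl3 at 12.04% ± 2.07, a gene model that overlaps Pth1r, and Tcap, a 1.143 kb gene that no peak touched. Of the marked members, Tnnc1 lies inside the gene model of Nisch, covered to 75.8%, and Xirp1 inside that of Cx3cr1, covered to 24.6%. Their peaks cannot be assigned to them alone. The list also holds Myocd, a transcriptional coactivator and not a sarcomere protein.

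**Figure D1:**
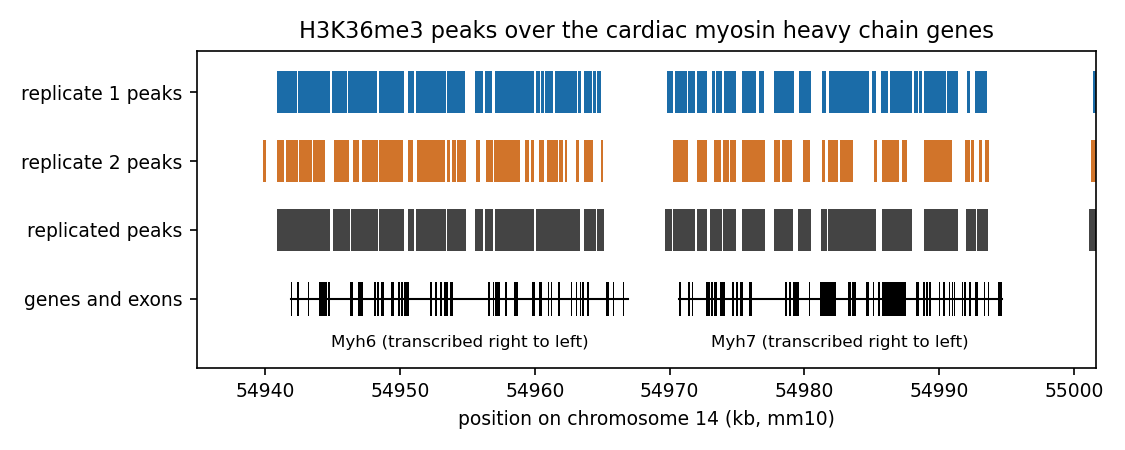
Peaks over the cardiac myosin heavy chain genes Myh6 and Myh7, with position on chromosome 14 in kb on the x axis and 1 row each for the 2 replicates, the replicated list and the exons of the genes (boxes). The 42 peaks of replicate 1, 48 of replicate 2 and 28 replicated peaks in the window fill most of both gene bodies and leave the 5' end of each gene, at its right, open.

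Transcription factor genes of heart development were marked less uniformly, in 14 of 24 cases. Gata6 (68.3% ± 2.08) and Tbx20 (61.0% ± 4.94) had the highest covered shares. Tbx5 was covered to 45.2% ± 5.65, Hand2 to 32.02% ± 7.17, Gata4 to 30.4% ± 4.83 and Nkx2-5 to 19.3% ± 1.36. Pitx2, a gene of left-right asymmetry, and Isl1, a marker of second heart field progenitors, were not touched by any peak in either replicate. Of the genes for calcium handling and conduction, 11 of 21 were marked. Atp2a2, encoding the calcium pump of the sarcoplasmic reticulum, reached 77.0% ± 3.35 and the potassium channel gene Kcnh2 39.9% ± 6.71. Ryr2, encoding the calcium release channel, had 20.5% ± 5.31 of a 553.8 kb gene body covered, and replicated peaks covered 24.04% of it, or 133.2 kb. Hcn1 and Sln had no covered base.

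Genes of the 5 other-tissue lists lay almost entirely outside the peaks. None of 22 hepatocyte, 22 skeletal muscle, 20 kidney and gut or 20 germ cell and pluripotency genes was marked. The liver gene Alb, the skeletal muscle regulator gene Myod1, Ryr1 and Pax7 had a covered share of 0 in both replicates. The highest values in these lists by replicated peaks were 7.76% of Vil1, 5.84% of the hepatocyte transcription factor gene Hnf1a and 5.28% of Lct. Hnf1a shares 804 bp with 2210016L21Rik, a gene covered to 56.7%. Of 24 neuronal genes, 1 was marked, the vesicular glutamate transporter gene Slc17a7. It lay just over the limit at 10.2% by replicated peaks and under it in both replicates (7.43% ± 2.45), while Nrxn1 and Grin2b had no replicated peak. Taking the 3 cardiac muscle lists together, 48 of 69 genes were marked, against 1 of 108 genes of the 5 other-tissue lists. The mean covered share was 31.7% against 0.274%, a difference of 31.5 percentage points (two-sided permutation test over genes, p = 2e-05, the smallest value that 100000 resamples can give). Fisher's exact test of the marked counts gave p = 1.96e-25 (two-sided). The difference was 30.8 points in replicate 1 and 25.2 in replicate 2, or 28.0 ± 3.95 (SD, n = 2). Genes are not independent replicates, so these p-values compare gene lists within these 2 libraries and do not measure the spread between animals. The comparison was not matched on gene length, and of the 3 cardiac lists only the sarcomere genes lay above their length-matched random range.

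Genes of the cell types that a whole heart also holds were marked in part, and 41.1% of all protein-coding genes were marked. Among random lists matched on gene length, the endocardial and endothelial count below stood at percentile 42.85. The epicardial, valve and mesenchymal count stood at 85.7 and the smooth muscle count at 65.2. By replicated peaks these 3 lists thus lay within their random ranges. Among endocardial and endothelial genes 8 of 20 were marked, led by Eng (41.1% ± 7.29) and Notch1 (32.1% ± 7.16), and Plvap and Robo4 had no replicated peak. This count depended on the library, with 13 marked by replicate 1 alone and 6 by replicate 2 alone. Epicardial, valve and mesenchymal genes were marked in 11 of 20 cases. Fn1, encoding fibronectin, was covered to 81.3% ± 3.01 and Vcan, encoding versican of the cardiac jelly, to 41.7% ± 4.41, whereas Aldh1a2 and Dcn had no replicated peak. Of 10 smooth muscle genes 5 were marked, Cnn1 (64.9% ± 9.08) and Smtn (65.3% ± 5.77) most fully, while Myh11 and Lmod1 were not touched. Erbb3 (20.5% ± 5.82) was the single marked gene of 10 neural crest and glial genes. Erythroid genes were marked in 4 of 18 cases, namely Alas2, Epor, Tal1 and Nfe2, and Alas2 lies within the gene model of Apex2. In replicate 2 alone that count fell to 1, below its random range, and the globin genes, all under 2 kb long, had no covered base. Of 18 macrophage and leukocyte genes 1 was marked by replicated peaks, Cd68, and 2 by replicate 2 alone, Cd68 and Csf1r. Cd68 was covered in full, and it lies 782 bp from Eif4a1, a translation factor gene covered to 67.2%. Csf1r overlaps Hmgxb3, covered to 88.2%.

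Genes used by most cells were marked without exception in 4 of the fixed lists. All 26 cell cycle genes, 24 translation and ribosome genes, 24 genes of oxidative phosphorylation and the citrate cycle, and 24 genes of the transcription and splicing machinery were marked, in each replicate. The cell cycle genes had the highest list median, 67.6% (mean of the 2 replicates' medians). The replication helicase genes Mcm2 (86.4% ± 3.06) and Mcm5 (83.0% ± 6.45) stood highest among them, and Bub1 (33.3% ± 1.66) and Pcna (31.5% ± 9.91) lowest. In the other 3 lists the highest members were Eef2 (83.1% ± 2.69) and Eif4g2 (78.9% ± 1.74), Ndufa10 (77.6% ± 5.57) and Uqcrc1 (82.3% ± 2.58), and Sf3a1 (88.9% ± 3.78) and Sf3b2 (83.4% ± 4.77). The lowest were Eef1a1 (14.54% ± 3.78) and Rpl3 (32.4% ± 0.256), Cox10 (13.1% ± 3.56) and Cox5a (24.3% ± 6.92), and Srsf11 (33.0% ± 1.67) and Srsf1 (30.4% ± 0.499). Genes for the enzymes and readers of H3K36 methylation were marked in 21 of 22 cases. The methyltransferase gene Setd2 had a covered share of 47.1% ± 5.82 and the demethylase gene Kdm4a 87.2% ± 2.81, followed by Brpf1 (65.7% ± 4.16). Setmar stood at 11.3% ± 0.105, and Phf19 (2.86% ± 0.426) was the member not marked. The reference genes Gapdh and Actb were covered to 38.6% ± 9.58 and 63.7% ± 1.55.

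Other families split sharply. None of 39 Hox genes and none of 20 replication-dependent histone genes had a covered base, and the longest of the latter, Hist1h2bc, is 8.71 kb. Of 1092 olfactory receptor genes none was marked and 1, Olfr543, had any covered base (5.12%). Zinc finger genes with a Zfp symbol were marked in 263 of 365 cases. Zfp869 (97.2% ± 0.966) and Zfp335 (86.8% ± 2.76) stood highest, and Zfp536 and Zfp936 had no replicated peak. Imprinted genes were marked in 12 of 25 cases, with Igf2r at 83.2% ± 5.62 and Nnat at 72.3% ± 18.4. Nnat lies inside Blcap, which was itself covered to 50.9%. Rasgrf1 and Dcn, a gene that is also in the mesenchymal list, had none. Against 10000 random lists of the same size and gene lengths, 7 of the 24 lists had more marked members than the range that held the middle 95% of them. These were the sarcomere, cell cycle, translation, oxidative phosphorylation, transcription and splicing, H3K36 enzyme and Zfp lists. Another 8 had fewer: macrophage and leukocyte, neuronal, hepatocyte, skeletal muscle, kidney and gut, germ cell, Hox and olfactory receptor genes. The other 9 lay within the range, among them the cardiac transcription factors at percentile 95.3 and the calcium handling and conduction genes at percentile 87.7. Neural crest and glial genes (percentile 1.6) and histone genes (percentile 1.7) lay at the lower bounds of their ranges, 1 and 0 marked members. The histone count could thus not fall below its range.

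**Figure D2:**
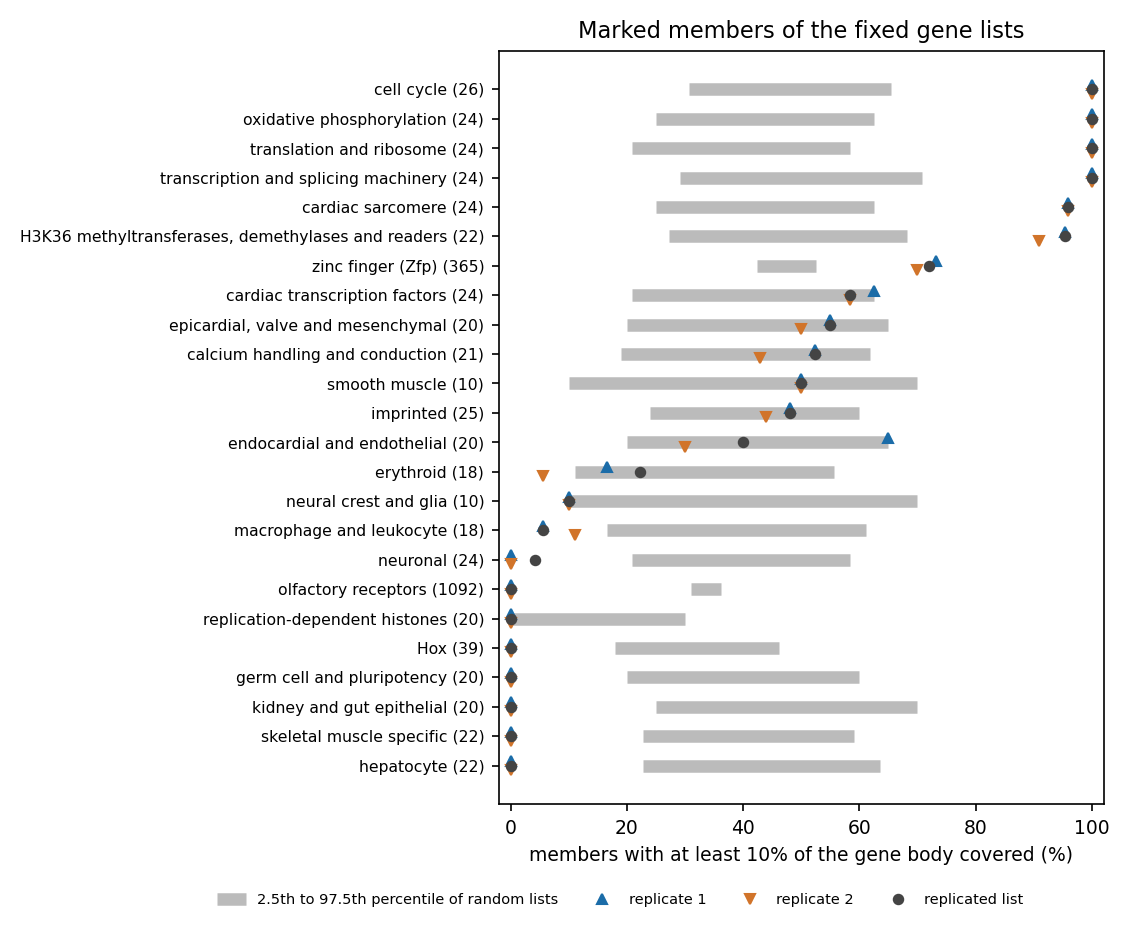
Share of each fixed gene list's members with at least 10% of the gene body covered (x axis, percent), by the replicated list (circles), replicate 1 (upward triangles) and replicate 2 (downward triangles), with the number of members in brackets. Grey bars give the range that held the middle 95% of 10000 random lists matched on gene length, and 7 lists lie above their bar and 8 below it by the replicated list.

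Over all 21911 protein-coding genes, 9008 (41.1%) were marked, and 8351 were marked in both replicates' own lists. The count was 9207 in replicate 1 and 8388 in replicate 2, 8797.5 ± 579.1 (SD, n = 2). After circular shifts of the replicated peaks along each chromosome, a mean of 3010 genes were marked (range 2810 to 3241 over 100 shifts). No replicated peak touched 10610 genes. Among genes of at least 10 kb the covered share was highest over Gpi1, encoding glucose-6-phosphate isomerase (chromosome 7, 34201330 to 34230336), at 92.3% ± 1.91. Ints1 (91.5% ± 2.41), Rnf40 (90.3% ± 3.88), Exosc10 (90.2% ± 1.96), Trrap (89.3% ± 4.05) and Prr12 (89.2% ± 1.72) came next when ranked by the mean of the replicates. The first 20 genes by replicated peaks also included Srp68, Copg1, Setd1a, Sin3b, Usp36, Mfn2, Ncapd2, Sec24c, Gtf3c1 and Kmt2b, as well as Sf3a1, Mcm2, Kdm4a and the sarcomere gene Mybpc3. They ranged from 90.03% for Kmt2b to 95.2% for Gpi1. By bases, the heart genes Ttn (211.0 kb of replicated peaks) and Ryr2 (133.2 kb) were among the 10 genes with the most covered sequence. So were Syne2 (159.4 kb), Fbn2 (146.9 kb), Vps13d (133.7 kb), Wdfy3 (130.4 kb), Eif4g3 (127.3 kb) and Fry (125.7 kb). The first 2 places in that order were held by Gm20388 and Fgfr2, annotated models of 4.43 and 2.96 Mb that overlap 73 and 30 other coding genes, so their peaks cannot be assigned to them. The marked share rose from 12.04% of the shortest of 10 length classes (up to 2.749 kb) to 54.3% of genes between 25.164 and 36.417 kb. It was 26.4% in the longest class, above 110.158 kb.

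Of the 10 replicated peaks with the highest signal value of the authors, whose scale is not stated, most lay in Zfp genes, and of the 100 highest 42 did. The highest value, 17.87, belonged to a peak of 5263 bp whose summit was in a coding exon of Zfp27 (chromosome 7, 29891674 to 29896936). Values of 17.6 for Zfp329 (chromosome 7, 12809255 to 12811676), 17.0 for 2610008E11Rik (chromosome 10, 79064109 to 79068064) and 17.0 for Zfp68 (chromosome 5, 138604732 to 138607933) followed, each with its summit in a coding exon. Zfp157, Zfp110 and Zfp810 and 2 further peaks in introns of Zfp68 were also among the first 10. The remaining peak, with its summit in a coding exon of Spred2, had a value of 15.8. The median over all replicated peaks was 3.38. The widest replicated peak, 34.948 kb, lay over Trrap (chromosome 5, 144821538 to 144856485). Ubr4 (31.919 kb), Gpi1 (26.667 kb), Kmt2d (25.916 kb) and Plec (25.016 kb) held the next widest.

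The next comparison asked where in the genome the peaks lay. Of the bases in each replicate's peaks, 95.2% ± 0.196 (SD, n = 2) were in annotated gene bodies, which make up 46.1% of the sequenced genome. The replicated peaks gave 95.3%, and 48.6% after circular shifts (range 46.5 to 51.1%). Coding exons held 10.8% ± 0.813 of peak bases in the replicates. By the replicated list their share was 7.56 times their share of the genome, and that of untranslated exons was 5.31 times and that of introns 1.74 times. The part of the 1 kb upstream of protein-coding genes that lies outside every annotated gene body held 0.0554% ± 0.00222 of peak bases. In the replicated list this was 0.0932 times its share of the genome. Intergenic sequence held 4.74% ± 0.194.

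Along genes of at least 5 kb (17779 genes) the coverage rose from the 5' end to the 3' end. In the first of 10 equal parts 3.06% ± 0.680 of bases were covered, in the fifth 20.1% ± 2.75 and in the last 26.9% ± 3.23. The last-to-first ratio was 8.26 in replicate 1 and 9.57 in replicate 2, 8.91 ± 0.927 (SD, n = 2), and 5.89 by replicated peaks in genes of at least 20 kb. Coverage reached its lowest value, 0.918% ± 0.138, in the 1 kb before the annotated start. Beyond the annotated end it was 22.3% ± 3.27 in the first kb and 12.6% ± 2.10 in the third. In the 8138 marked genes of this length it rose from 6.10% ± 1.30 in the first part to 57.8% ± 6.27 in the ninth, and was 43.7% ± 6.03 in the first kb past the end. The rise was larger than the SD in both gene sets and was present in each replicate. No test between positions was made.

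**Figure D3:**
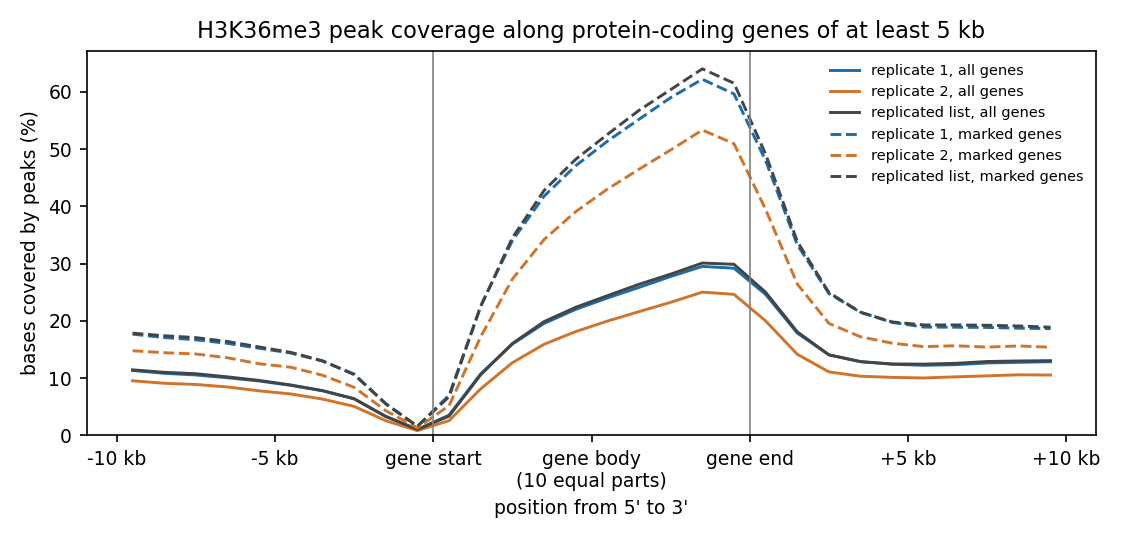
Mean share of bases covered by peaks (y axis, percent) in 10 equal parts of the gene body and in 1 kb steps of the 10 kb on either side, 5' to 3' on the x axis, for all 17779 genes of at least 5 kb (solid) and the 8138 marked ones (dashed). Lines stand for replicate 1, replicate 2 and the replicated list, which rises from 3.36% in the first part to 30.1% in the ninth over all genes.

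Within marked genes exons were covered more than introns, with the first exon and intron left out. Over 7985 genes the median covered share was 68.2% of exonic and 51.1% of intronic bases by replicated peaks. The median difference per gene was 12.7 ± 0.289 percentage points (SD, n = 2, mean of the replicates), and exons were covered more in 73.1% of genes by replicated peaks. Internal exons had a median width of 137 bp and replicated peaks of 557 bp, so a peak over an exon usually reaches into introns. The last exon was kept and coverage rose towards the 3' end, so the place of exons along the gene may add to the difference. This was not tested.

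Gene bodies on the X chromosome were covered less than those of the autosomes. Peaks covered 2.73% ± 0.873 of protein-coding gene bases on the X and 11.4% ± 1.82 on the autosomes. The ratio was 0.263 in replicate 1 and 0.209 in replicate 2, 0.236 ± 0.0387 (SD, n = 2). Among X-linked genes 17.5% were marked, against 42.6% of autosomal genes. Chromosome 11 had the highest value, 15.9% ± 2.33, and chromosome 14 the lowest of the autosomes, 8.39% ± 1.48. None of 183 genes on the Y was marked. The embryos were pooled over both sexes, so the copy number of the X was not known.

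**Figure D4:**
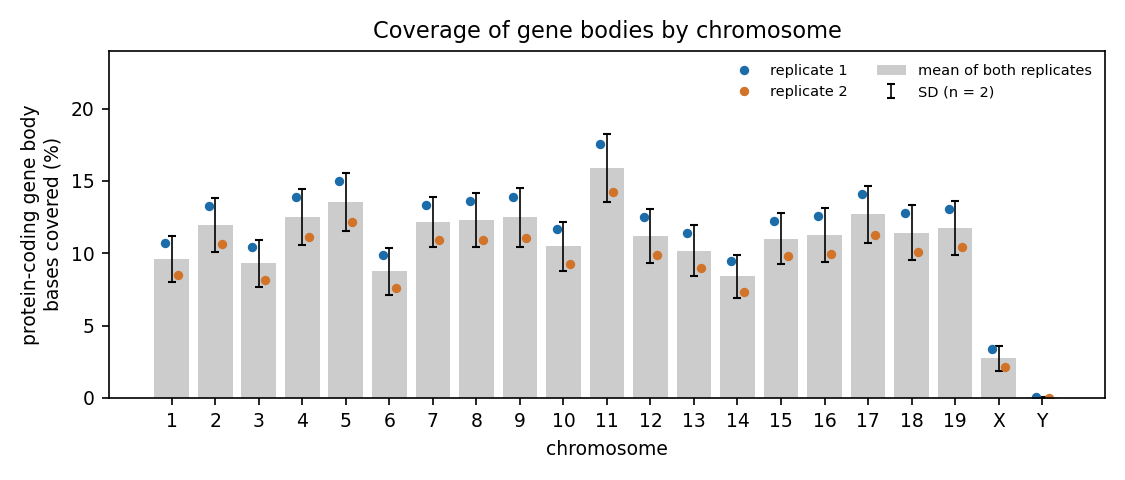
Share of protein-coding gene body bases covered by peaks on each chromosome (y axis, percent). Bars give the mean of the 2 replicates with their SD (n = 2) and points the single replicates; the X stands at 2.73% and the autosomes between 8.39% and 15.9%.

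The last comparison asked how far the replicates agreed. At an overlap of at least 1 bp, 86.2% of the peaks of replicate 2 met a peak of replicate 1, and 67.5% of the peaks of replicate 1 met a peak of replicate 2. After circular shifts these shares were 8.44% and 7.23%. The shared bases made up 60.7% of the bases in either list, against 2.59% after shifts. Across the 21911 genes the covered shares had a Pearson r of 0.985 and a Spearman rho of 0.976, given without a p since genes are not independent replicates. Replicate 1 had the higher covered share in 8546 of the 9008 marked genes (94.9%), with medians of 42.9% and 34.3%. Among genes of at least 10 kb the largest differences were 27.5 percentage points for Mtfr2, 25.6 for Tkfc, 25.5 for Dhodh, 24.4 for the X-linked Gpkow and 24.4 for Slc25a19. In the other direction Acot13 (15.7% and 24.2%) and Hook2 (0 and 8.45%) differed most, followed by Isg20l2, Rida and Fcer2a.

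Of the pooled peaks, 70.1% were in the replicated list. The share rose with the authors' signal value, from 26.1% in the lowest quintile to 99.96% in the highest, and with width, from 15.5% to 99.97%. Of the 64174 pooled peaks that were not in it, 54.4% met a peak of replicate 1 only and 20.9% of replicate 2 only.

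**Figure D5:**
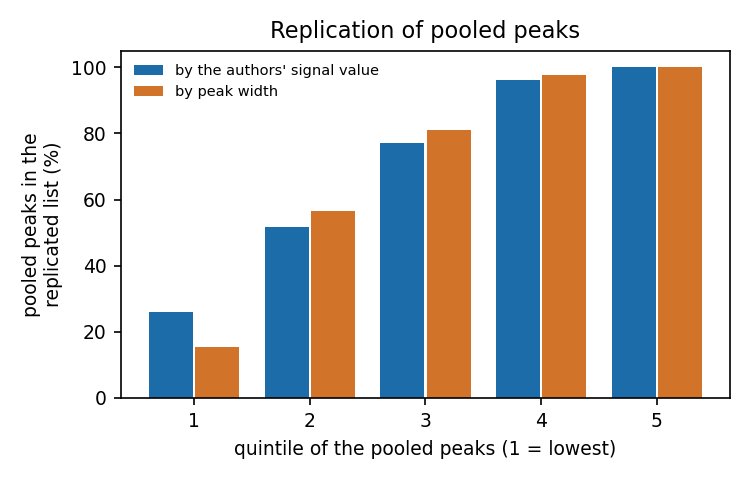
Share of the pooled peaks that are in the replicated list (y axis, percent) by quintile of the authors' signal value and of peak width within the pooled list (x axis, 1 is the lowest). By signal value the share is 26.1%, 51.6%, 77.0%, 96.0% and 99.96% from the first to the last quintile.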

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

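Outside the chromosomes used in the comparisons, 19 replicated peaks lay on 4 sequences that are not placed within a chromosome. They covered 14044 bp, with a highest signal value of 8.51, and the replicates' own lists held 34 and 24 such peaks. They are given because no comparison used them. No control was analysed here, so their level over background is unknown.

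The other patterns weighed here are the zinc finger genes among the strongest peaks, the wider coverage in replicate 1 and the lower coverage of the X. The tests were chosen before their results were seen, except the gene length test and the strongest-peak signal ratio on the X. Both were added after other results for the X had been seen. The rule for reading the GC and cluster tests of the zinc finger genes was also changed after their values were seen. With 1 group in the series no biological explanation was tested for any of them, and intervals are 95% bootstrap intervals over genes or peaks.

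Of the 100 replicated peaks with the highest signal value, 42 lay in Zfp genes, which hold 1.75% of all replicated peaks. The strongest peaks of marked Zfp genes had a median of 2.65% (2.03 to 3.41) of 31-base words that occur more than once in the genome, which argues against reads shared between near-identical gene copies for these genes as a set. For the 32 of them whose strongest peak is among those 100 the median was 2.71%, with single genes from 0 to 24.8%, so shared reads at single genes stay open. The strongest-peak signal of marked Zfp genes exceeded that of other marked genes by 1.07 at the median, and 62.7% (41.7 to 91.6) of this difference was left within classes of GC content and peak width, and 74.8% (31.3 to 108.4) for the 85 genes with no other Zfp gene within 500 kb. Both intervals exclude the 20% or less that a whole cause would leave, but neither meets the bound set at first, an interval wholly above 50%, under which both were undecided, so each may account for part of the pattern, and background in the controls stays open.

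Replicate 1 had the higher covered share in 94.9% of marked genes. At equal signal value its −log10 p was higher in each of 5 classes, with a median ratio of 1.272 (range 1.19 to 1.29). Deeper sequencing or a more sensitive call would give this. Replicate 1 combined 2 technical replicates and replicate 2 had 1, but the number of reads in each is unknown. Among the 117652 peaks of replicate 1 that met just 1 peak of replicate 2, the signal values were not higher in replicate 1 (median ratio 0.998, 0.996 to 0.999). These peaks had to pass replicate 2's own call, which may lower the ratio, so a higher enrichment in replicate 1 stays open. GC content had a Spearman rho of 0.0395 (0.0179 to 0.0611) with the difference across genes, too weak to be the cause. These tests rest on a signal value whose scale is not stated, and a difference between the pools of embryos, which may also widen the calls, stays open.

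The X chromosome had a lower covered share even among marked genes, by a median difference of -17.6 percentage points (-21.6 to -13.2), which argues against a lower number of active genes as the whole cause. Within classes of gene length the difference was -17.7 points (-22.6 to -14.7), which argues against longer genes. At equal signal value the −log10 p on the X was 0.888 times that on the autosomes (median of 5 classes). The ratio was 0.939 in the highest class, which holds only 2 peaks of the X, and 0.846 to 0.898 in the others. The next highest class holds only 6 peaks of the X. Less sensitive peak calling on the X cannot be told apart from a lower mark. The strongest peaks of marked X genes had 0.755 times the signal of autosomal ones (0.709 to 0.785). The embryos were pooled over both sexes, so the copy number of the X is not known and may lower the call, which stays open.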

How the results depend on the processing

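All alternatives were planned. A result with a p-value counts as kept when its direction and its side of 0.05 stay the same, a count when it stays within 1.5 times the reported count, and any other value when it moves by less than 1 SD of the replicates. By these limits 52 of the 66 alternative values of the comparisons were kept and 14 moved. A reversal could be recorded only for results with a p-value, and none of these reversed. For the X to autosome ratio the reported value is the mean of the replicates, so leaving out either replicate was bound to keep it. The limits for counts and p-values are wider than the replicate spread, and single gene lists did change side of their random range, as given below. Where a value moved, the cause was not tested unless the setting itself gives it. No paired analysis was possible because the series holds only 1 group. The overlap, the agreement across genes and the replicated share need both replicates, so neither could be left out there, and these were held to a 95% interval over peaks or genes.

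Requiring 50% of the shorter peak lowered the overlap from 86.2% to 81.8% of replicate 2's peaks and from 67.5% to 63.3% of replicate 1's. A −log10 p of at least 5 gave 86.0% and 64.3%, and the top 50000 peaks of each list 75.8% and 66.1%. With that stricter −log10 p the Spearman rho was 0.969 and the replicated share 82.8%, and over genes that overlap no other the rho was 0.974. The share of peak bases in gene bodies was 94.97% in the pooled list and 94.7% by peak midpoints. The last-to-first ratio along genes fell to 7.70 in the pooled list and to 5.89 in genes of at least 20 kb. Leaving out a replicate gave an exon minus intron difference of 12.4 to 13.0 percentage points, a gene body share of 95.1 to 95.3%, a last-to-first ratio of 8.26 to 9.57 and an X to autosome ratio of 0.209 to 0.263.

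The share of genes that were marked, 41.1%, ranged from 31.7% at a level of 25% (6941 of 21911) to 51.6% at 1 bp (11301 of 21911). Over genes that overlap no other it was 36.7% (6308 of 17191). The count was 8388 without replicate 1 and 9207 without replicate 2. The cardiac minus other-tissue difference stayed between 25.2 and 34.2 percentage points, with a permutation p of 2e-05 under each alternative that applies to it, the smallest it can give. Lists above their random range numbered 7 to 10 and below it 8 to 10. The lists that changed side all lay within the range at first. With the pooled list cardiac transcription factors (17 of 24) and endocardial and endothelial genes (14 of 20) moved above it, and neural crest and histone genes below. At 1 bp cardiac transcription factors (18 of 24), calcium and conduction genes (19 of 21) and endocardial and endothelial genes (16 of 20) moved above. At 25% these 3 lists fell to 10, 6 and 4 marked members but stayed within the range, and neural crest and erythroid genes moved below it, both with 0 marked. Without replicate 1 erythroid genes (1 of 18) moved below, and with random lists of any length histone genes did.

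By the same limits 23 of 192 alternative counts of marked list members moved, and 132 of 508 alternative covered shares of named genes. A count can also move because fewer members are eligible, as for the oxidative phosphorylation genes that overlap no other, of which 15 of 15 were marked. The read depth behind each list is unknown, so a gene without a peak is not shown to lack the mark. In the pooled list, called on both replicates together, 14 endocardial and endothelial genes were marked against 8 by the replicated list.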

Other observations

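Several further genes of the embryonic heart differed widely, and all of these were chosen after their values were seen. Des, encoding the muscle intermediate filament desmin and a member of the smooth muscle list, was covered to 59.2% ± 7.83 (SD, n = 2) and Fhl2 to 35.2% ± 2.62. The splicing regulator gene Rbm20 had 17.8% ± 5.18 and Ankrd1 18.1% ± 0.565. Nppa and Nppb, which encode natriuretic peptides and are 1.36 and 1.42 kb long, had no covered base in either replicate, and Mb, encoding myoglobin, had 2.31% ± 1.80. Of the genes known from growing embryonic tissues, Igf2bp1 was covered to 49.7% ± 4.84, Igf2bp3 to 22.1% ± 4.57 and Hmga2 to 10.6% ± 4.93, while Lin28b had 0.895% ± 0.536. Dmd, a gene of 2257 kb on the X, had 0.0203% of its body in replicated peaks.

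Long non-coding genes that overlap no protein-coding gene were marked in 136 of 6028 cases (2.26%), with 152 by replicate 1 and 123 by replicate 2. Those of at least 10 kb with the highest covered share by replicated peaks were AU020206 (58.2% ± 14.1), 1700020I14Rik (51.7% ± 4.26), Mirg (49.5% ± 13.97), Gm39469 (48.2% ± 3.19) and Meg3 (41.4% ± 22.9). Mirg and Meg3 lie in the same imprinted region of chromosome 12 as Rian, which had 17.7% ± 6.34. The neighbouring genes Malat1 and Neat1 on chromosome 19 had 59.3% ± 2.92 and 1.76% ± 1.33. These values describe peaks over annotated bodies and were not tested.

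Outside every annotated gene 3194 regions of replicated peaks, joined over gaps of up to 3 kb, covered 3.51 Mb. The nearest end of a protein-coding gene was a 3' end for 2985 of them (93.5%), and by this nearest end 2868 lay within 10 kb of a 3' end and 111 within 10 kb of a 5' end. The 215 regions further than 10 kb from any protein-coding gene covered 0.138 Mb. The most covered of these, 6.27 kb in 9 peaks, lay on chromosome 17 (22722564 to 22737576) between Vmn2r112 and Zfp945. The next, of 3.65 kb, lay on chromosome 5 (104584978 to 104589132) between BC005561 and Zfp951.

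Of the replicated peaks 85.6% touched a peak in both replicates' own lists, and 72.4% were covered to 50% or more in each. The rule by which the authors called a peak replicated was not given in the sources used here, so the others were not examined further.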
